A study of Mus musculus with 9 samples.

How the data were processed

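RNA was sequenced from tumour, tumour-adjacent and tail tissue of 3 mice, which gave 9 libraries in 3 groups of 3. The authors deposited a table of expected counts per gene and library, that is, estimated counts that need not be whole; 70.4% of the values above 0 were exactly whole as deposited, with no tolerance. Bowtie 0.12.2 and GRCm39 were named per the submitters' processing notes, without a role for either, and the program that made the counts was not given in the sources used here. The table held 57214 loci, of which 3514 carried no gene name. These unnamed loci were left out of the library sizes and tests, and the 53700 named genes were kept. The authors' group means were not used. Gene types came from GENCODE M21, matched by gene ID for 52093 named genes (97.0%). M21 describes an earlier mouse assembly, so no coordinates were used. No human reference was used here, and reads were not separated by species here. Whether the submitters removed reads of the human graft before counting was not given in the sources used here.

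Total counts per library ran from 3836830 in tumour replicate 3 to 26039643 in adjacent replicate 3, with 16151 to 22569 named genes at 1 count or more. After TMM scaling a gene without counts was below 1.00 CPM in tumour replicate 3 and 0.0932 CPM in tail replicate 3, the extremes over libraries (upper 95% limit of a count of 0). Scaling factors by TMM were 1.20, 1.13 and 0.801 for tumour libraries 1 to 3, 0.541, 0.745 and 0.782 for adjacent and 1.43, 1.44 and 1.42 for tail libraries. No library pair differed by as little as counting noise. The common biological coefficient of variation was 0.500.

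Counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr on tissue with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood F test, Benjamini-Hochberg). The filter kept 17886 genes with 99.9% of named counts. Genes were called at an adjusted p under 0.05. All 9 libraries shared the spread, with tissue and replicate number as terms. The replicate block rests on the series text, which says that tissues of each mouse were compared; it does not say outright that the number in a title is the mouse. The pairing was checked: after removal of tissue means, correlations across genes between libraries with the same number lay between -0.0758 and 0.0974, none above 0.1. The same number gave the best correlation in 3 of 3 tumour to tail pairs, 3 of 3 adjacent to tail pairs and 0 of 3 tumour to adjacent pairs, so the values gave a hint of the pairing with tail only. Counts without the block are given in the closing part. The standard error of a log2 fold change was its size divided by the square root of its F statistic.

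Gene lists, 33 in number, were chosen before the data were examined, for the pathways of clear cell renal carcinoma, for cell types that each tissue piece could hold, for genes nearly identical in human and mouse and for rodent-expanded families. Each list was described by its called members, by its members adjusted over the list alone, and by camera (limma 3.58.1, correlation preset to 0.01, Benjamini-Hochberg over lists). Camera with an estimated correlation and fry were run beside it. With an estimated correlation no list was called in any comparison. For adjacent tissue against tail this included lists with every tested member called. These were respiratory chain (24 of 24, estimated correlation 0.453) and epidermis (19 of 19, estimated correlation 0.565). The lack of a call by this variant therefore does not separate lists that moved from lists that did not. The named genes of each comparison were the 5 highest and 5 lowest called genes that changed the same way in all 3 replicates, with at least 20 CPM in the higher group and no predicted name; up to 3 called members of each list with the largest changes and at least 10 CPM, with the list's most abundant member; and Vegfa, Car9, Mki67, Vhl, Epas1, Hif1a and Foxn1. Symbols on more than 1 locus numbered 81 and were kept apart by gene ID. Single-gene values of a few genes named by this rule are not reported here.

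The procedure was tested on simulated data with the depths and spread of these libraries and 50 changed genes per size. Apart from the changed genes, all simulated tissues had the same mean levels, and no replicate effect was put in. The simulation therefore does not test the scaling where tissues differ in as many genes as here. At log2 changes of 2, 4, 6 and 8 edgeR recovered 18, 86, 100 and 98% of them for tumour against adjacent tissue, 30, 78, 96 and 98% against tail and 38, 92, 96 and 100% for adjacent tissue against tail, with 5, 8 and 10 false calls (DESeq2: 101, 93 and 121). Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, no replicate block, a test against a log2 fold change of 1, the tissues compared alone, and each library and each mouse left out in turn. Keeping the unnamed loci and leaving out annotated pseudogenes were chosen after seeing the data. Copies of mitochondrial genes among the pseudogenes (20 of the 13493) were found by sequence and left out of the pseudogene shares.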

Results

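Bulk RNA sequencing was performed on 3 tissues of nude mice that carried a human kidney tumour graft. Cells of 786-O, an established human clear cell renal carcinoma line that lacks a working VHL tumour suppressor, were injected under the skin of the right back of 10 male BALB/c nude mice, a strain that lacks a thymus and has few mature T cells. Tumours grew in 7 mice, and 3 mice with tumours of 1 to 1.5 cm in diameter were sequenced one month later. Each mouse gave a tumour, tumour-adjacent tissue from more than 1 cm beyond the capsule, and 0.5 cm of tail taken before the injection, so the 9 libraries formed 3 groups of 3. The labels gave a postnatal age of 28 days to all libraries, and the mice were bought at 4 weeks of age. Tumour and adjacent tissue were taken one month after the injection, when the mice were older than that label. Which tissue surrounded the tumours was not given in the sources used here.

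The deposited table held estimated counts on mouse genes. Total counts were 12034408, 12197119 and 3836830 in the tumour libraries 1 to 3, 23508124, 24669826 and 26039643 in the adjacent libraries and 18333498, 20321131 and 22853716 in the tail libraries. Mitochondrially encoded genes took 1.81, 1.90 and 0.800% of the counts in tumour, 13.2, 9.66 and 10.5% in adjacent tissue and 5.17, 7.34 and 4.89% in tail. Tumour replicate 3 was the shallowest library, where a gene without counts was below 1.00 CPM after scaling, against 0.0932 CPM in tail replicate 3, the deepest after scaling. How the submitters handled reads of the human graft was not given in the sources used here. Its transcripts could enter the table only where they were counted on a mouse gene, so each tumour value describes mouse cells, human reads counted on mouse genes, or a mixture. Levels below are means ± SD over the 3 libraries of a tissue (n = 3), in CPM after TMM scaling. Log2 fold changes are given ± their standard error.

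**Figure D1:**
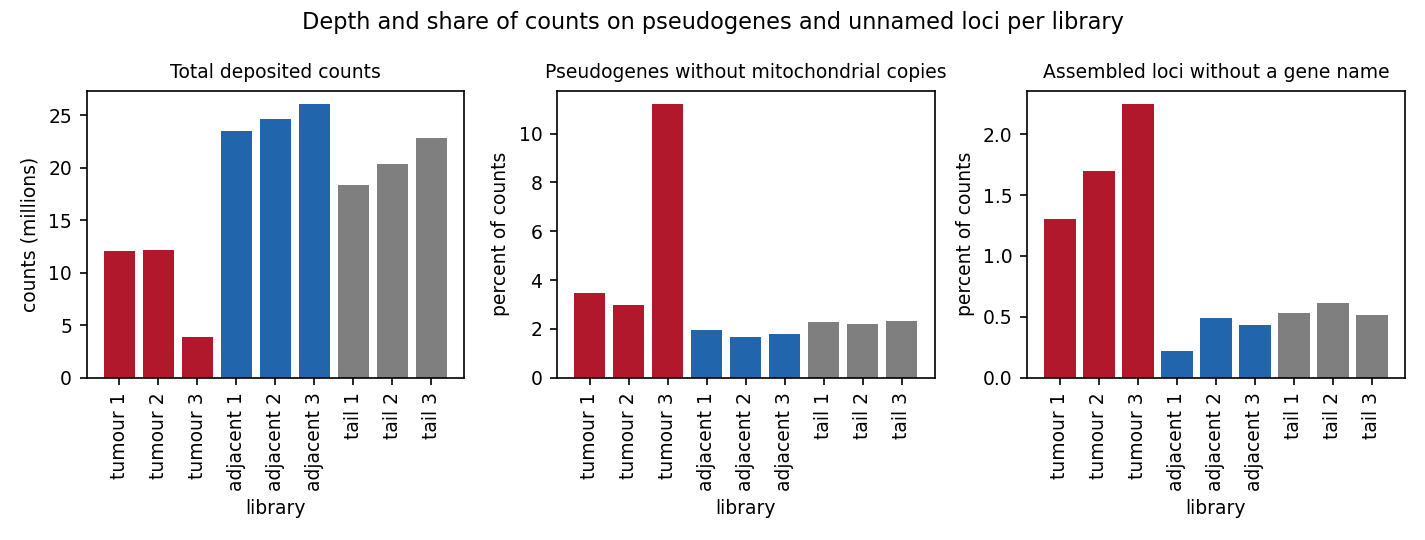
Total deposited counts in M, the share of counts on annotated pseudogenes (percent of counts outside mitochondrial genes and their copies) and the share on loci without a gene name (percent of all counts), each on a vertical axis from 0, with a bar per library on the horizontal axis. Pseudogenes took 3.47, 2.96 and 11.2% in tumour libraries 1 to 3, 1.96, 1.66 and 1.80% in adjacent and 2.28, 2.19 and 2.34% in tail libraries.

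**Figure D2:**
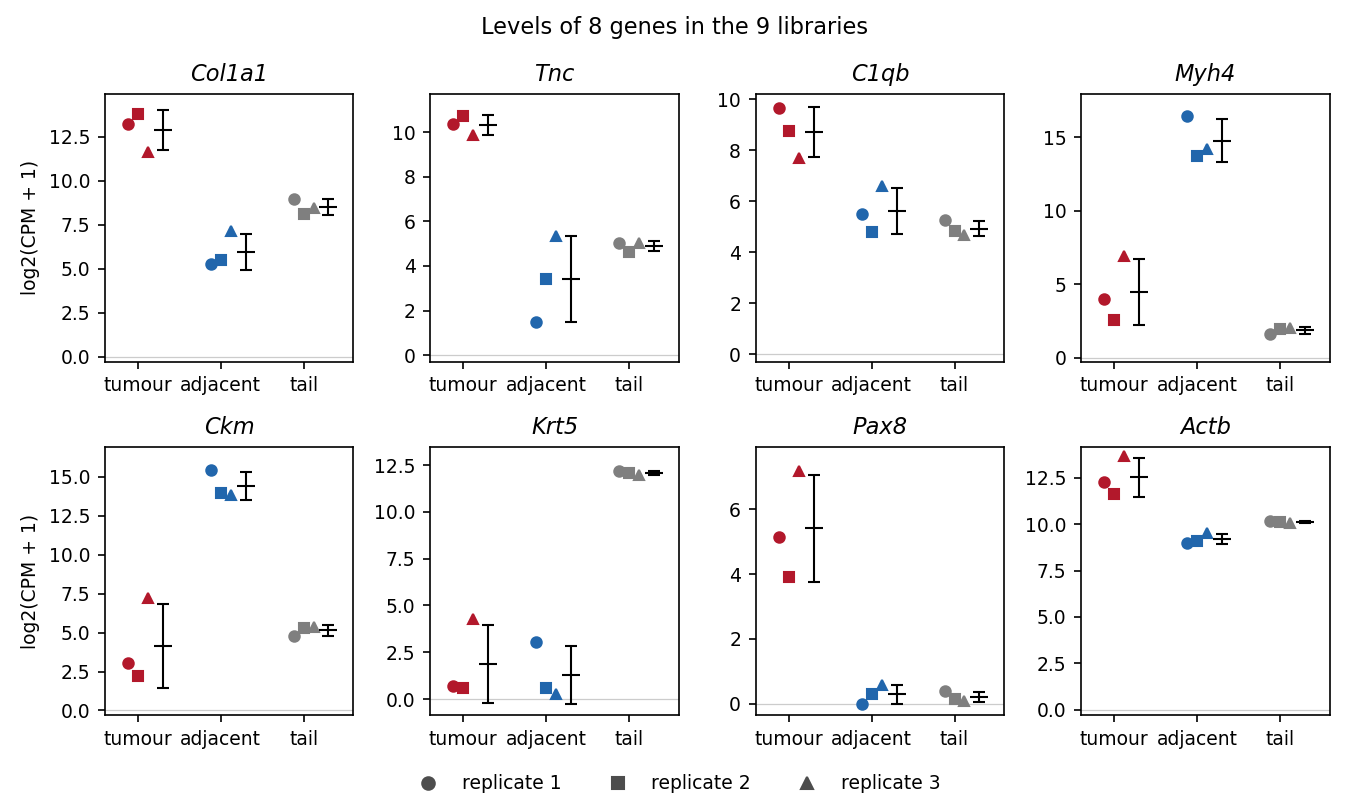
Levels of 8 genes in each library, as log2(CPM + 1) on the vertical axis, by tissue on the horizontal axis; symbols are the replicates, and black bars give the mean ± SD. Col1a1 lay between 3184 and 14459.6 CPM in tumour and at most 504 CPM in the other tissues, while Myh4 stood out in adjacent tissue and Krt5 in tail.

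The first comparison set tumour against adjacent tissue of the same mice, to describe how the tumours differed from their surroundings. Fibrillar collagen and other matrix transcripts were among those far higher in tumour. Col1a1, which encodes a chain of type I collagen (ENSMUSG00000001506), reached 9063 ± 5653 against 73.5 ± 57.1 CPM and was 130.4-fold higher. Skeletal muscle transcripts were abundant in adjacent tissue instead: Myh4, the fast myosin heavy chain IIb (ENSMUSG00000057003), stood at 39927 ± 41436 CPM there and at 45.6 ± 62.4 CPM in tumour. The called members of the macrophage, antigen presentation and cytokine lists were all higher in tumour (12 of 20, 5 of 15 and 6 of 19 members), and those of the respiratory chain and adipocyte lists all lower (23 of 24 and 8 of 16). No list kept its camera call with an estimated correlation, where the lowest adjusted p was 0.771. Of 17886 genes tested, 3069 were higher and 3257 lower in tumour with edgeR's quasi-likelihood test (Benjamini-Hochberg), and 8396 had an unadjusted p under 0.05.

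In the matrix and activated fibroblast list, 21 of 24 genes were higher in tumour and 0 lower, with 22 and 0 adjusted over the list alone (camera adjusted p = 2.82e-09, adjusted p = 0.771 with an estimated correlation). Col12a1, a collagen of dense connective tissue, rose from 13.6 ± 9.51 to 1859 ± 1696 CPM, a log2 fold change of 7.05 ± 0.88. Tnc, the matrix glycoprotein tenascin C, rose from 17.0 ± 20.05 to 1317 ± 384 CPM (log2 fold change 6.82 ± 1.10). Among bone list genes, 4 of 10 were higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.178). They included Col1a1 and the osteoclast genes Ctsk and Acp5, at 497 ± 499 and 181 ± 142 CPM in tumour. Col11a1, a fibrillar collagen of the cartilage list, rose by 6.82 ± 0.75 on the log2 scale. The matrix count was 13 without mouse 1.

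Of the macrophage list, 12 of 20 genes were higher in tumour and 0 lower, with 15 and 0 adjusted over the list alone (camera adjusted p = 0.000283, adjusted p = 0.771 with an estimated correlation). Ms4a7 rose from 3.32 ± 2.34 to 58.4 ± 62.2 CPM, Adgre1, which encodes the F4/80 antigen, from 5.75 ± 3.79 to 76.3 ± 79.6 CPM, and Trem2 from 7.61 ± 6.76 to 73.6 ± 46.0 CPM. Apoe, the most abundant member, reached 5479 ± 3600.3 against 525 ± 82.5 CPM. Chemokines included Cxcl9, a ligand of CXCR3 induced by interferon gamma, with a log2 fold change of 6.31 ± 1.31, and Ccl5 and Cxcl10, with 4.78 ± 0.92 and 4.78 ± 1.17. In the cytokine and chemokine list 6 of 19 genes were higher and 0 lower, with 6 and 0 adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.771 with an estimated correlation). Antigen presentation genes were higher for 5 of 15 members and lower for 0, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.0123, adjusted p = 0.779 with an estimated correlation). The class II gene H2-Aa rose by 3.31 ± 0.96 on the log2 scale, and the invariant chain Cd74 stood at 3525, 29.5 and 219 CPM in tumour replicates 1 to 3. Interferon response genes were higher for 3 of 19 members and lower for 0, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.00218, adjusted p = 0.771 with an estimated correlation). Of the NK cell list, 1 of 6 genes was higher and 0 lower, with 1 and 0 adjusted over the list alone (camera adjusted p = 0.0371, adjusted p = 0.771 with an estimated correlation). Its most abundant member Nkg7 was at 24.9, 0.959 and 0.669 CPM in the tumour libraries, not past the test. The macrophage count was 0 without mouse 1, 1 without mouse 2, 6 without adjacent 1 and 5 without adjacent 2. The cytokine count was 1 without mouse 1, 3 without mouse 2 or tumour 1 or adjacent 2, 11 without mouse 3 and 10 without tumour 3. The antigen presentation count was 2 without mouse 1 or tail 3 and 0 without tumour 1 or adjacent 1 or 2. The interferon count was 0 without mouse 1 or adjacent 2, 1 without mouse 2 or tumour 1 or 2 or adjacent 1 or tail 1, 14 without mouse 3, 16 without adjacent 3 and 6 without tail 3. The NK cell count was 0 without mouse 1 or tumour 1 or adjacent 1, 4 without mouse 3 or adjacent 3, 3 without tumour 3 and 2 without tail 2. The macrophage count without tumour replicate 3 was 17.

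Skeletal muscle genes were lower in tumour for 20 of 24 members and higher for 0, with 0 and 20 adjusted over the list alone (camera adjusted p = 4.63e-08, adjusted p = 0.771 with an estimated correlation). Atp2a1, the calcium pump of fast fibres, stood at 114 ± 186 CPM in tumour against 38281 ± 19642 CPM in adjacent tissue, and Ckm, muscle creatine kinase, at 53.1 ± 82.7 against 25071 ± 17032 CPM. The 5 lowest genes by the naming rule were Dhrs7c, Lrrc14b, Mstn, Lsmem1 and Nmrk2, all without counts in the tumour libraries and at least 1852-, 1301-, 922-, 370.0- and 345-fold lower, against a floor of 3 counts over the group. With the library left out that lowered each limit most, they were 700.0-fold for Dhrs7c, 73.0-fold for Lsmem1 and 175-fold for Nmrk2 without adjacent 1 and 700.2-fold for Lrrc14b and 496-fold for Mstn without tumour 1. Such floors, like the 95% counting intervals, cover counting error alone. Mstn encodes myostatin, a secreted inhibitor of muscle growth. The muscle list's median level differed among the tumour libraries, at 3.70, 0.922 and 115 CPM in replicates 1 to 3. Nuclear-encoded respiratory chain genes were lower for 23 of 24 members, with 0 and 23 adjusted over the list alone (camera adjusted p = 1.48e-09, adjusted p = 0.771 with an estimated correlation). Ndufa4, a subunit linked to cytochrome c oxidase, fell by 3.87 on the log2 scale and Ndufb5, of complex I, by 3.44. Mitochondrially encoded genes were lower for 10 of 12 members, with 0 and 11 adjusted over the list alone (camera adjusted p = 2.13e-05, adjusted p = 0.771 with an estimated correlation). The cytochrome oxidase gene mt-Co1 stood at 5668 ± 1763 against 58263 ± 23927 CPM. Adipocyte genes were lower for 8 of 16 members, with 0 and 10 adjusted over the list alone (camera adjusted p = 0.000553, adjusted p = 0.771 with an estimated correlation). Plin4, a lipid droplet protein, was at 7.93 ± 6.50 against 1167 ± 254 CPM. Clock genes were lower for 9 of 16 members and higher for 1, with 1 and 10 adjusted over the list alone (camera adjusted p = 0.0139, adjusted p = 0.771 with an estimated correlation). The output transcription factor Tef fell by 3.07, Ciart fell by 2.53 and Npas2, a partner of the BMAL1 protein, rose by 4.59. The muscle count was 4 without mouse 1. The respiratory chain count was 15 without mouse 1. The mitochondrially encoded count was 5 without mouse 1. The adipocyte count was 5 without mouse 3 or tumour 3 and 14 without tumour 1. The clock count was 3 without mouse 1.

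Hypoxia and HIF target genes moved both ways, with 9 of 23 higher, 5 lower and 10 and 6 adjusted over the list alone (camera adjusted p = 0.785). Slc2a1, the GLUT1 glucose transporter, rose from 27.5 ± 14.6 to 247 ± 153 CPM, and Angptl4 and Hilpda rose by 3.47 ± 1.14 and 2.98 ± 0.76 on the log2 scale. In replicate 3 Angptl4 went the other way, at 15.4 CPM in tumour against 23.7 CPM in adjacent tissue. Hk2, a hexokinase of both this and the glycolytic list, fell by 2.46. Vegfa, which encodes the main endothelial growth factor, was at 132 ± 70.8 against 189.6 ± 12.0 CPM and not called, with edgeR quasi-likelihood adjusted p = 0.250. Hif1a rose to 266 ± 73.5 against 46.1 ± 14.2 CPM, while Epas1, which encodes HIF-2 alpha, was at 117 ± 36.8 against 212 ± 73.6 CPM and Vhl at 27.4 ± 11.2 against 12.9 ± 2.56 CPM, neither past the test. Car9 was at 9.69 ± 13.8 against 0.802 ± 0.646 CPM, not called. In the glycolytic list 5 of 15 genes were higher and 3 lower, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.981). The muscle-rich Aldoa was at 1455 ± 905 against 20093 ± 7600.0 CPM and Pgam1 rose by 2.98 ± 0.54. Cell cycle genes were higher for 6 of 26 members and lower for 0, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.771 with an estimated correlation). Top2a, DNA topoisomerase II alpha, rose from 12.1 ± 10.2 to 115 ± 66.6 CPM and the mitotic regulator Foxm1 from 4.68 ± 4.43 to 32.1 ± 16.2 CPM, whereas Mki67, the proliferation marker, was at 53.8 ± 46.4 against 23.3 ± 20.2 CPM and not called. The higher hypoxia count was 2 without mouse 1 or 2, 4 without tumour 2, 5 without adjacent 1 and 1 without adjacent 2. The lower hypoxia count was 3 without mouse 1 or 3. The higher glycolytic count was 3 without mouse 1. The lower glycolytic count was 1 without mouse 1 or 2. The cell cycle count was 1 without mouse 1 and 3 without mouse 3 or tumour 1 or 3.

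Genes of renal carcinoma cells were higher in tumour for 10 of 18 members and lower for 0, with 11 and 0 adjusted over the list alone (camera adjusted p = 0.00138, adjusted p = 0.771 with an estimated correlation). Pax8 and Pax2 encode transcription factors of the renal lineage, and Krt8 a simple epithelial keratin. Pax8 was at 34.5, 14.1 and 144 CPM in tumour replicates 1 to 3 and 0.238 ± 0.247 CPM in adjacent tissue. Pax2 had no counts in adjacent tissue and was at least 361-fold higher in tumour, or 86.8-fold without tumour replicate 3 (1.97, 8.19 and 53.2 CPM in tumour replicates 1 to 3), and Krt8 rose by 7.98 ± 0.99 on the log2 scale. Genes whose coding sequence is nearly the same in human and mouse were higher for 14 of 33 members and lower for 1, with 14 and 1 adjusted over the list alone (camera adjusted p = 0.00138, adjusted p = 0.771 with an estimated correlation). Eef1a1, a translation elongation factor, was at 12626, 11072 and 50959.7 CPM in tumour replicates 1 to 3 against 1611 ± 719 CPM in adjacent tissue, and Actb at 7107 ± 5311 against 596 ± 120.1 CPM. Cytosolic ribosomal protein genes were higher for 7 of 23 members and lower for 0, with 9 and 0 adjusted over the list alone (camera adjusted p = 0.00272, adjusted p = 0.771 with an estimated correlation). Rps18 was at 4483 ± 5738 against 14.7 ± 4.88 CPM, with 1438, 909.996 and 11102 CPM in tumour replicates 1 to 3. It was at 12.6, 20.3 and 11.2 CPM in adjacent libraries 1 to 3 and 17.7 ± 2.20 CPM in tail. Rplp0, of the same list, stood at 1073 ± 294 CPM in adjacent tissue and 1028 ± 53.3 CPM in tail. Whether reads of Rps18 were lost or placed on other loci was not tested, so the size of its change is uncertain. The 5 highest genes by the naming rule were the annotated pseudogenes Rpl10-ps1, Rpl7a-ps3, Bnip3l-ps, Rps12-ps24 and Ap3m1-ps, without counts in adjacent tissue and at least 7807-, 902-, 596-, 444- and 389.9-fold higher. These limits rested largely on tumour replicate 3, and were 671-fold for Rpl10-ps1, 302-fold for Rpl7a-ps3, 19.96-fold for Bnip3l-ps, 14.7-fold for Rps12-ps24 and 116-fold for Ap3m1-ps without tumour 3. Counts on such copies are uncertain, since reads of near-identical genes could be placed on any of them. Of 1038 pseudogenes tested, 492 were higher and 61 lower in tumour. The renal carcinoma count was 5 without mouse 1 and 6 without mouse 2. The conserved count was 0 without mouse 1, 5 without mouse 2, 8 without adjacent 1, 2 or 3 and 7 without tail 2. The lower conserved count was 0 without mouse 1 or 2 or tumour 1, 3 without mouse 3 and 5 without tumour 3. The ribosomal count was 1 without mouse 1 or 2, 4 without mouse 3 or tumour 1, 2 without adjacent 1, 2 or 3 and 3 without tail 1, 2 or 3.

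The count of called genes depended on single mice: it was 2504 without mouse 1, 3169 without mouse 2, 4110 without adjacent replicate 2 and 6817 without tumour replicate 3. A fit of the tumour and adjacent libraries alone called 3755 genes, and a test against a log2 fold change of 1 called 3529.

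**Figure D3:**
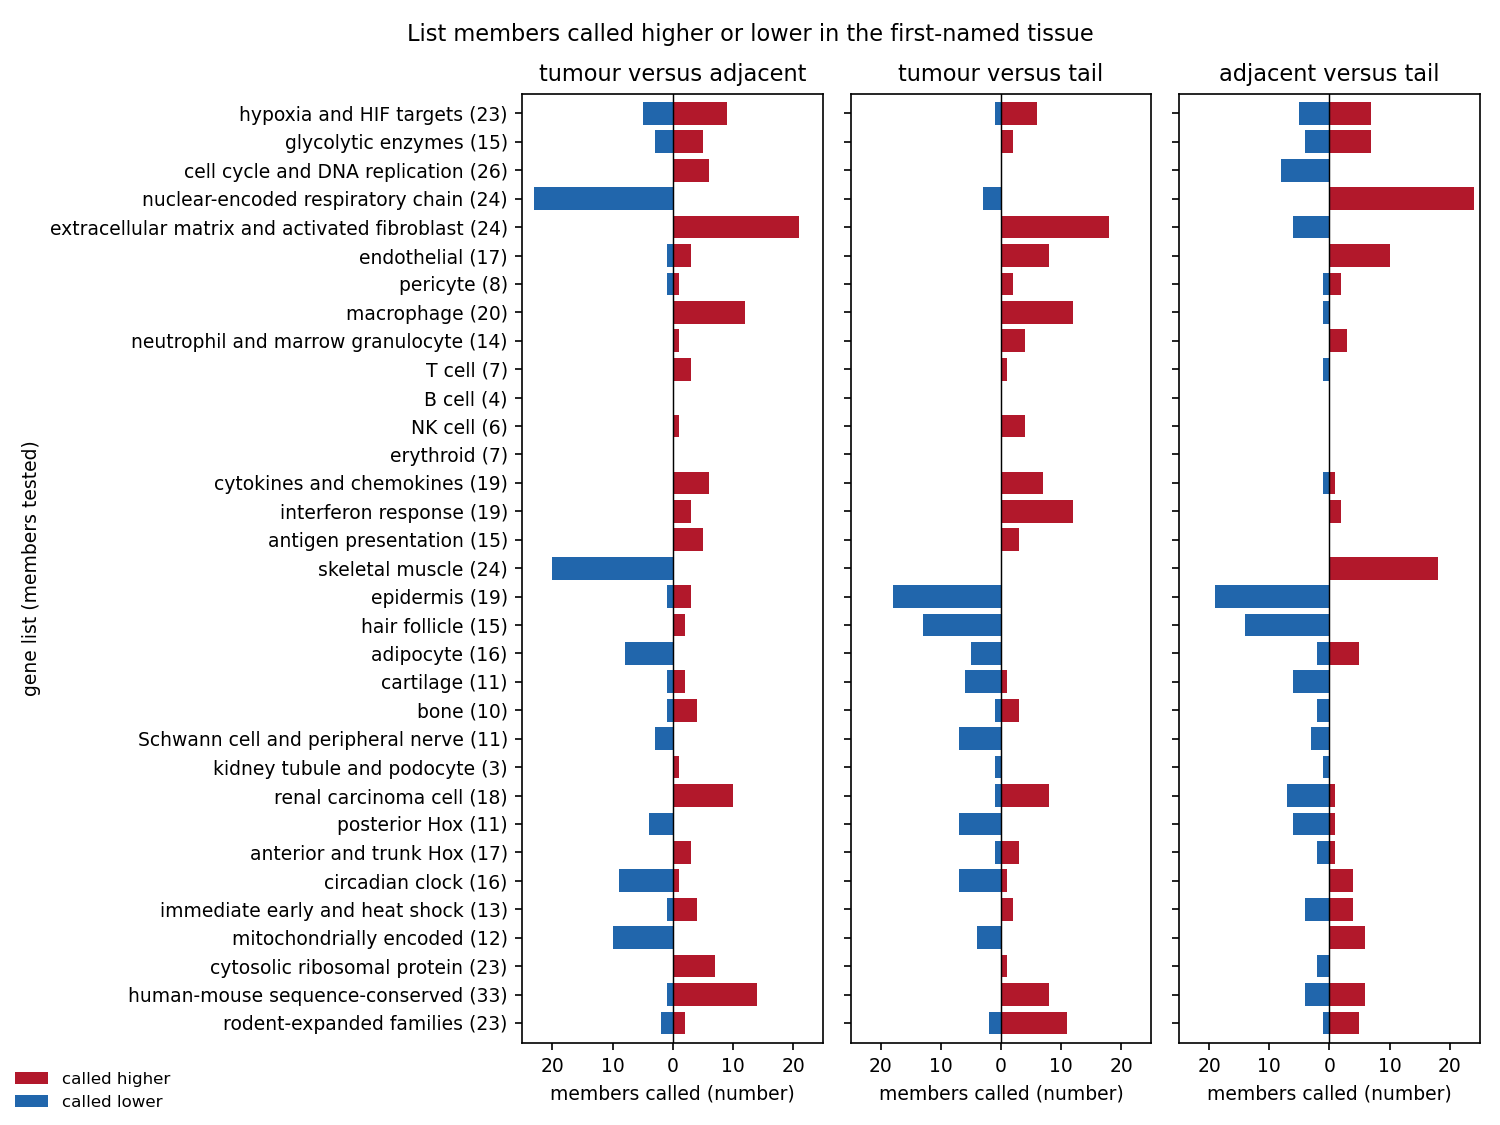
Number of members called higher (to the right of 0) or lower (to the left) in the tissue named first, on the horizontal axis, for each of the 33 gene lists on the vertical axis, with the members tested in brackets; each panel is a comparison. Matrix genes were called higher in tumour against adjacent tissue (21 of 24) and against tail (18 of 24), and epidermis genes lower in tumour (18 of 19) and adjacent tissue (19 of 19) against tail.

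The second comparison set tumour against the tail piece of the same mice. Tissue and time could not be separated here, because the tail was cut before the injection. Most epidermis and hair follicle genes tested were lower in tumour (18 of 19 and 13 of 15), and most matrix, macrophage and interferon response genes higher (18 of 24, 12 of 20 and 12 of 19). No list kept its camera call with an estimated correlation, where the lowest adjusted p was 0.448. Krt5, the keratin of basal epidermal cells (ENSMUSG00000061527), was at 6.41 ± 10.1 against 4309.9 ± 291 CPM, and Col1a1 at 9063 ± 5653 against 378 ± 116 CPM. Of 17886 genes, 2292 were higher and 2297 lower in tumour with edgeR's quasi-likelihood test (Benjamini-Hochberg), and 7496 had an unadjusted p under 0.05.

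Epidermis genes were lower for 18 of 19 members and higher for 0, with 0 and 19 adjusted over the list alone (camera adjusted p = 4.02e-13, adjusted p = 0.556 with an estimated correlation). Krt1, of the upper epidermis, was at 1.88 ± 3.01 against 3157 ± 246 CPM. Dsc1, the desmosomal cadherin desmocollin 1, had no counts in tumour and was at least 1932-fold lower, and Flg, filaggrin, had 1 count in tumour, a ratio of 0.000102 to tail (95% counting interval 2.59e-06 to 0.00057). Among hair follicle genes 13 of 15 were lower and 0 higher, with 0 and 15 adjusted over the list alone (camera adjusted p = 3.23e-12, adjusted p = 0.448 with an estimated correlation). Krt71 and Krt31, keratins of the hair root sheath and shaft, and Hoxc13 had no counts in tumour, and were at least 957-, 330.1- and 579.7-fold lower. Krt24, Defb6, Cyp4f39 and Lypd3 completed the 5 lowest genes by the naming rule, each at least 1103- to 1604-fold lower. Foxn1, the gene disrupted in nude mice, was at 21.3 ± 0.706 CPM in tail and had no counts in the 6 other libraries, at least 219-fold lower in tumour. Without tumour replicate 1, which leaves a higher floor, these limits were 1039.9-fold for Dsc1, 515-fold for Krt71, 178-fold for Krt31, 312-fold for Hoxc13, 594-fold for Cyp4f39, 863-fold for Defb6, 660.2-fold for Krt24, 674-fold for Lypd3 and 118-fold for Foxn1. Posterior Hox genes, which mark the hind end of the body axis, were lower for 7 of 11 members, with 0 and 10 adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.573 with an estimated correlation). Hoxc12 had 1 count in tumour, a ratio of 0.00130 (95% counting interval 3.29e-05 to 0.00725). Cartilage genes were lower for 6 of 11 members and higher for 1, with 1 and 9 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.556 with an estimated correlation). Col2a1, type II collagen, was at 0.148 ± 0.256 against 14.3 ± 2.67 CPM. Schwann cell and nerve genes were lower for 7 of 11 members, with 0 and 8 adjusted over the list alone (camera adjusted p = 0.000321, adjusted p = 0.448 with an estimated correlation). Adipocyte genes were lower for 5 of 16 members, with 0 and 5 adjusted over the list alone (camera adjusted p = 0.00721, adjusted p = 0.652 with an estimated correlation). Scd1, stearoyl-CoA desaturase, which sebaceous glands also express, fell by 6.47 on the log2 scale. The posterior Hox count was 2 without mouse 1 or tail 1 or 2, 4 without mouse 2 or tumour 1 and 3 without tail 3. The cartilage count was 0 without mouse 1, 3 without mouse 2 or 3 or tail 2 and 2 without tail 1 or 3. The Schwann cell count was 4 without mouse 3 or tail 1 or 3. The adipocyte count was 3 without mouse 3 and 8 without tumour 1.

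Matrix genes were higher in tumour for 18 of 24 members, with 20 and 0 adjusted over the list alone (camera adjusted p = 2.21e-10, adjusted p = 0.556 with an estimated correlation). Tnc rose from 29.1 ± 4.62 to 1317 ± 384 CPM and Col12a1 from 64.6 ± 5.86 to 1859 ± 1696 CPM. Endothelial genes were higher for 8 of 17 members, with 12 and 0 adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.577 with an estimated correlation). Esm1 and Apln, markers of sprouting vessels, rose by 5.07 ± 0.65 and 4.43 ± 1.01 on the log2 scale, and Cdh5, VE-cadherin, by 3.13 ± 0.63. Hypoxia and HIF targets were higher for 6 of 23 members and lower for 1, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0212, adjusted p = 0.663 with an estimated correlation). Adm and Angptl4 rose by 3.93 ± 0.86 and 3.51 ± 1.04, Vegfa rose to 132 ± 70.8 against 35.8 ± 3.36 CPM, and Car12, which tail skin held at 288 ± 31.4 CPM, fell by 5.85. Epas1 and Hif1a rose by 1.28 ± 0.36 and 1.04 ± 0.30, while Vhl, with a log2 fold change of 1.15 ± 0.42, Car9, with 1.44 ± 1.33, and Mki67, with -1.69 ± 1.36, were not called. Glycolytic genes were higher for 2 of 15 members, with 0 and 0 adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.577 with an estimated correlation). These were Slc16a3, a lactate transporter, and Pkm, at 3836 ± 2702 against 664 ± 22.4 CPM. The matrix count was 11 without mouse 1, 4 without mouse 2 and 10 without tail 2 or 3. The endothelial count was 3 without mouse 1, 2 or 3, 2 without tumour 1, 14 without adjacent 1 and 1 without tail 1, 2 or 3. The hypoxia count was 2 without mouse 2 or tail 1, 2 or 3. The glycolytic count was 1 without mouse 1 or adjacent 2 or tail 3, 0 without mouse 2 or 3 or tumour 2 or tail 1 or 2 and 4 without tumour 1 or adjacent 1.

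Macrophage genes were higher in tumour for 12 of 20 members, with 17 and 0 adjusted over the list alone (camera adjusted p = 5.83e-06, adjusted p = 0.577 with an estimated correlation). Fcgr1, an Fc receptor, was at 87.3 ± 89.8 against 2.47 ± 0.650 CPM, and the complement gene C1qb at 485 ± 309 against 30.0 ± 6.81 CPM. Interferon response genes were higher for 12 of 19 members, with 16 and 0 adjusted over the list alone (camera adjusted p = 3.49e-07, adjusted p = 0.577 with an estimated correlation). Rsad2, viperin, was at 18.6 ± 10.6 against 1.05 ± 0.280 CPM, and Ifi44 rose by 4.02 ± 1.01 on the log2 scale. Cytokine and chemokine genes were higher for 7 of 19 members, with 7 and 0 adjusted over the list alone (camera adjusted p = 0.000321, adjusted p = 0.577 with an estimated correlation). Cxcl9 was at 413, 31.2 and 43.8 CPM in tumour replicates 1 to 3 against 0.124 ± 0.215 CPM in tail. NK cell genes were higher for 4 of 6 members, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.556 with an estimated correlation). The median of that list was 14.9, 1.99 and 1.34 CPM in tumour replicates 1 to 3 and 0, 0.0862 and 0.0311 CPM in tail. The value of tumour replicate 3 rests on 2 to 6 counts per member. Antigen presentation genes were higher for 3 of 15 members, with 3 and 0 adjusted over the list alone (camera adjusted p = 0.00581, adjusted p = 0.652 with an estimated correlation). These were B2m, Tapbp and the immunoproteasome gene Psmb8. Genes of rodent-expanded families, most of them of myeloid cells, were higher for 11 of 23 members and lower for 2, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.000101, adjusted p = 0.577 with an estimated correlation). Saa3, an acute-phase serum amyloid, was at 560.4 ± 578 against 0.543 ± 0.197 CPM and Chil3 at 87.8 ± 24.5 against 0.531 ± 0.433 CPM. Renal carcinoma genes were higher for 8 of 18 members and lower for 1, with 9 and 1 adjusted over the list alone (camera adjusted p = 0.00265, adjusted p = 0.556 with an estimated correlation). Igfbp3, a binding protein of insulin-like growth factors, was at 1509 ± 378 against 60.7 ± 14.0 CPM. Conserved genes were higher for 8 of 33 members, with 7 and 0 adjusted over the list alone (camera adjusted p = 0.000102, adjusted p = 0.577 with an estimated correlation). Actb rose by 2.45 ± 0.58. The 5 highest genes by the naming rule were again annotated pseudogenes, Rpl10-ps1, Rps12-ps10, Hspd1-ps3, H3f3a-ps1 and Rpl19-ps6, at least 2577- to 13310.5-fold higher. These limits also rested largely on tumour replicate 3, and were 1144-fold for Rpl10-ps1, 1715-fold for Rps12-ps10, 1667-fold for Hspd1-ps3, 725-fold for H3f3a-ps1 and 598-fold for Rpl19-ps6 without tumour 3. In all, 508 of 1038 pseudogenes were higher and 58 lower. Mitochondrially encoded genes were lower for 4 of 12 members, with 0 and 6 adjusted over the list alone (camera adjusted p = 0.00273, adjusted p = 0.577 with an estimated correlation). Immediate early and heat shock genes were higher for 2 of 13, with 2 and 0 adjusted over the list alone (camera adjusted p = 0.0213, adjusted p = 0.556 with an estimated correlation), namely for Jun and Dusp1. The macrophage count was 1 without mouse 1, 4 without mouse 2 or tumour 1, 5 without tumour 2 or tail 2 and 2 without tail 1 or 3. The interferon count was 3 without mouse 1, 4 without tumour 1 or 2 and 2 without tail 1 or 3. The cytokine count was 4 without mouse 1 or 2 or tail 1 or 3 and 13 without tumour 3. The NK cell count was 0 without mouse 1 and 1 without mouse 2 or tumour 1 or tail 1 or 3. The antigen presentation count was 0 without mouse 1 or 2 or tumour 1 or tail 1 or 3, 5 without tumour 3 and 1 without adjacent 2 or tail 2. The rodent-expanded count was 5 without mouse 1 or tail 1, 7 without tumour 1 and 3 without tail 3. The renal carcinoma count was 5 without mouse 1 or tumour 1 or 2, 4 without mouse 2 or tail 2 and 3 without tail 3. The conserved count was 1 without mouse 1, 0 without mouse 2 or tail 1, 2 or 3, 2 without mouse 3 or tumour 1 and 4 without adjacent 2. The mitochondrially encoded count was 1 without mouse 1 or 3 or tumour 1 or tail 1, 2 or 3 and 2 without mouse 2 or adjacent 2 or 3. The immediate early and heat shock count was 1 without mouse 1 or 3 or tail 3, 0 without mouse 2 and 4 without tumour 3.

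Leaving out a library moved the count of called genes to 1955, 1848 and 1659 for tail replicates 1 to 3 and to 2665 and 4719 for tumour replicates 1 and 3, and leaving out a whole mouse moved it to 1665, 1762 and 2771. A test against a log2 fold change of 1 called 2392 genes.

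Genes that set the tumour apart from both other tissues were counted next. Of the genes named above, Col1a1, Col12a1, Tnc, Ctsk, Col11a1, Ms4a7, Adgre1, Trem2, Cxcl9, Ccl5, Cxcl10, Angptl4, Hif1a, Pax8, Pax2, Krt8, Actb, Rps18, Esm1, Apln, C1qb, Tapbp and Igfbp3 were called higher in tumour in both comparisons, as were the pseudogenes Rpl10-ps1, Rpl7a-ps3, Bnip3l-ps, Rps12-ps24, Ap3m1-ps, Rps12-ps10, Hspd1-ps3, H3f3a-ps1 and Rpl19-ps6. Of these, Angptl4 was not higher in tumour than in adjacent tissue in replicate 3 (15.4 against 23.7 CPM). Rps18 was highest in tumour replicate 3, at 11102 CPM. Whether read placement held Rps18 low in the other tissues was not tested. Called lower in both were Dhrs7c, Mstn, Nmrk2, Ndufa4, Ndufb5, Plin4, Tef, Ciart and Cyp4f39. Some of these were low in a second tissue too. In tail libraries 1 to 3 Dhrs7c was at 0.689, 0.241 and 0.497 CPM and Mstn at 0.230, 0.482 and 0.746 CPM. Nmrk2 was at 0.498, 0.827 and 1.09 CPM there, and Cyp4f39 at 3.78, 0.876 and 0.889 CPM in adjacent libraries 1 to 3. Most of these values lie below 1.00 CPM, the limit for a gene without counts in tumour replicate 3. In all, 1472 genes were higher in tumour than in both tissues and 824 were lower. Independent lists of the same sizes would share 393 and 418 genes. Simulated tissues without any effect that shared the tumour libraries gave 0 shared calls in each of 20 simulations. Without any effect hardly any gene is called, so this count could hardly differ from 0. It does not gauge the overlap among genes that do differ. Part of the excess may still come from the shared tumour libraries, since 3 libraries could not be split. Pseudogenes made up 449 of the 1472 higher and 17 of the 824 lower genes. The higher and lower counts were 784 with 325, 700 with 264 and 596 with 254 without tail replicates 1, 2 and 3, and 534 with 163, 597 with 200 and 1076 with 482 without mice 1, 2 and 3. They were 851 with 372 and 1120 with 533 without tumour replicates 1 and 2 and 1006 with 459 without adjacent replicate 2. In each of these the lower count fell by a larger ratio than the higher one. Without adjacent replicate 1 the counts were 1099 with 633, and there the higher count fell by the larger ratio. The total was 2556 without tumour replicate 3 and 1865 with the annotated pseudogenes left out, an alternative chosen after seeing the data.

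The last comparison set the adjacent tissue against the tail piece, 2 non-tumour tissues taken a month apart. Most skeletal muscle and respiratory chain genes tested were higher in adjacent tissue (18 of 24 and 24 of 24), and most epidermis and hair follicle genes lower (19 of 19 and 14 of 15). No list kept its camera call with an estimated correlation, where the lowest adjusted p was 0.839. This held even for the respiratory chain and epidermis lists, with every tested member called. Mybpc2, the fast form of myosin-binding protein C (ENSMUSG00000038670), was at 6565 ± 5568 against 0.367 ± 0.0198 CPM, and the basal keratin gene Krt5 at 2.70 ± 4.08 against 4309.9 ± 291 CPM. Of 17886 genes, 2622 were higher and 2697 lower in adjacent tissue with edgeR's quasi-likelihood test (Benjamini-Hochberg), and 7552 had an unadjusted p under 0.05.

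Skeletal muscle genes were higher in adjacent tissue for 18 of 24 members, with 20 and 0 adjusted over the list alone (camera adjusted p = 1.71e-05, adjusted p = 0.848 with an estimated correlation). Myh4 was at 39927 ± 41436 against 2.62 ± 0.523 CPM and Actn3, the alpha-actinin of fast fibres, at 11402 ± 9973 against 5.23 ± 1.55 CPM. Asb11 and Lrrc14b, also among the 5 highest genes by the naming rule, were at 456 ± 79.9 and 127 ± 36.5 CPM in adjacent tissue. Every respiratory chain gene tested was higher, 24 of 24, with 24 and 0 adjusted over the list alone (camera adjusted p = 1.38e-10, adjusted p = 0.839 with an estimated correlation). Cox5a, of cytochrome c oxidase, rose by 2.71 ± 0.45 on the log2 scale and Sdhb, of succinate dehydrogenase, by 2.43 ± 0.35. Mitochondrially encoded genes were higher for 6 of 12 members, with 7 and 0 adjusted over the list alone (camera adjusted p = 0.000404, adjusted p = 0.848 with an estimated correlation). Cytochrome b, mt-Cytb, was at 14708 ± 4468 against 2293 ± 349.9 CPM. Endothelial genes were higher for 10 of 17 members, with 12 and 0 adjusted over the list alone (camera adjusted p = 0.00324, adjusted p = 0.848 with an estimated correlation). The junction and receptor genes Cdh5, Flt1 and Pecam1 rose by 3.64 ± 0.65, 3.25 ± 0.57 and 2.69 ± 0.68. Marrow granulocyte genes were higher for 3 of 14 members, with 5 and 0 adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.848 with an estimated correlation). Retnlg, of neutrophils, stood at 0.867, 38.5 and 12.0 CPM in adjacent replicates 1 to 3. Genes of rodent-expanded families were higher for 5 of 23 members and lower for 1, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.848 with an estimated correlation). Chil3 stood at 2.36, 132 and 190.3 CPM. The muscle count was 5 without mouse 1, 9 without adjacent 2 or tail 3 and 6 without tail 1. The respiratory chain count was 6 without mouse 1 or 2, 11 without tail 1 and 12 without tail 2. The mitochondrially encoded count was 0 without mouse 1 or 2 or tail 1, 2 or 3 and 3 without adjacent 1. The endothelial count was 2 without mouse 2 or adjacent 2 or tail 1, 2 or 3, 3 without mouse 3 and 6 without adjacent 3. The granulocyte count was 1 without mouse 2 or adjacent 2 or tail 1 or 2, 5 without tumour 1 or adjacent 1 and 6 without tumour 3. The rodent-expanded count was 2 without mouse 2 or adjacent 3, 0 without mouse 3, 10 without adjacent 1, 3 without adjacent 2 or tail 1 or 2 and 1 without tail 3.

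All 19 epidermis genes tested were lower in adjacent tissue, with 0 and 19 adjusted over the list alone (camera adjusted p = 1.94e-09, adjusted p = 0.839 with an estimated correlation). Hair follicle genes were lower for 14 of 15, with 0 and 14 adjusted over the list alone (camera adjusted p = 1.55e-09, adjusted p = 0.839 with an estimated correlation). Krt35, a hair shaft keratin, Msx2 and Krt27 had no counts in adjacent tissue and were at least 5639.7-, 827- and 470.5-fold lower. The desmosomal cadherin gene Dsg3 and Them5, Lypd3 and Aadacl2fm2 completed the 5 lowest by the naming rule. Posterior Hox genes were lower for 6 of 11 members and higher for 1, with 1 and 6 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.839 with an estimated correlation). Hoxd11 and Hoxc12 were at least 242- and 430.5-fold lower, while Hoxc10 rose to 105 ± 47.9 against 6.02 ± 1.11 CPM. The limits of this paragraph were lowest at 3409-fold for Krt35, 499.8-fold for Msx2, 284-fold for Krt27, 146-fold for Hoxd11 and 260.2-fold for Hoxc12 without adjacent 3. Cell cycle genes were lower for 8 of 26 members, with 0 and 15 adjusted over the list alone (camera adjusted p = 3.06e-05, adjusted p = 0.848 with an estimated correlation). Kif11, Ccnb1, which encodes cyclin B1, and Top2a fell by 3.30, 3.26 and 3.17 on the log2 scale. Matrix genes were lower for 6 of 24 members, with 0 and 4 adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.848 with an estimated correlation). Postn, periostin, was at 38.6 ± 39.3 against 363 ± 33.2 CPM. Cartilage genes were lower for 6 of 11 members, with 0 and 8 adjusted over the list alone (camera adjusted p = 0.00176, adjusted p = 0.839 with an estimated correlation). Schwann cell genes were lower for 3 of 11, with 0 and 4 adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.839 with an estimated correlation). Comp, a cartilage matrix protein, fell by 4.33. Vegfa, at 189.6 ± 12.0 against 35.8 ± 3.36 CPM, was higher in adjacent tissue, as was Epas1, by 2.12 ± 0.37, whereas Hif1a fell by 1.48. Car9 and Vhl, with log2 fold changes of -1.53 ± 1.15 and 0.09 ± 0.41, and Mki67, with -2.95 ± 1.39, were not called. The posterior Hox count was 3 without mouse 1 or tail 1. The cell cycle count was 5 without mouse 1 or 3, 1 without mouse 2 or adjacent 2, 13 without tumour 1, 0 without tail 1 or 2 and 3 without tail 3. The matrix count was 0 without mouse 1 or tail 1, 1 without mouse 2 or adjacent 2 or tail 3, 2 without adjacent 1, 12 without adjacent 3 and 3 without tail 2. The cartilage count was 2 without mouse 1 or tail 1 and 3 without mouse 3 or adjacent 1 or 3 or tail 3. The Schwann cell count was 0 without mouse 1, 1 without mouse 2 or tail 2 and 5 without tumour 2 or 3.

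The count of called genes was 2119 without mouse 1, 2111 without mouse 2, 2951 without adjacent replicate 2, and 2385, 2485 and 2711 without tail replicates 1, 2 and 3. A test against a log2 fold change of 1 called 2838 genes.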

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

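The test of unnamed loci was written before its result was seen; the pseudogene share without mitochondrial copies and the comparison of pseudogenes with their parent genes were chosen only after the result was seen. Loci without a gene name, which were left out of the comparisons except in the alternative that keeps them, took 1.30, 1.70 and 2.25% of all counts in tumour libraries 1 to 3, against 0.217, 0.491 and 0.433% in adjacent tissue and 0.531, 0.611 and 0.513% in tail. The signal lies outside the named genes and above the level of the other tissues. Of 3514 such loci, 132 had at least 10 counts in each tumour library, and 0 of these had no counts in the other 6 libraries.

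A candidate explanation is RNA of the human graft cells counted on mouse loci. It needs each tumour share above each other share and the highest in tumour replicate 3, and the lowest tumour share was 2.13 times the highest other share. Among named genes, the pseudogene share without mitochondrial copies gave a ratio of 1.27 by the same measure, with 11.2% in tumour replicate 3, where the conserved list had a median of 1481 CPM against 586 and 505 CPM in tumour replicates 1 and 2; with the mitochondrial copies kept, the shares were 3.98, 3.57 and 11.4% in tumour, 6.62, 5.004 and 5.77% in adjacent tissue and 4.29, 4.94 and 4.21% in tail, which do not separate tumour libraries 1 and 2. Reads shared with the mouse parent gene cannot be told apart from this: over all 181 pseudogenes named for a tested parent, copy minus parent in fitted log2 fold change, tumour against tail, had a median of 3.71 with quartiles of -0.25 and 9.60, so some copies moved with the parent and others far from it, and a changed share of an abundant parent's reads would raise a copy near 0 with the parent unmoved. A first version of this test, over the 98 copies called higher alone, gave a median of 9.33 (quartiles 6.44 and 11.09) and had been read as evidence against shared reads. It was replaced, with its bounds, once both values were known, because it picked copies by the outcome it tested. Also open is a difference of tissue itself, since every tumour library holds graft cells and no library of the same tissue lacks them.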

How the results depend on the processing

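Keeping the unnamed loci and leaving out annotated pseudogenes were alternatives chosen after seeing the data. In the order tumour against adjacent, tumour against tail, adjacent against tail and tumour against both, the called genes numbered 6326, 4589, 5319 and 2296 as reported, 6404, 4688, 5342 and 2369 with RLE size factors, 8253, 6723, 6995 and 3626 with DESeq2, 5714, 4136, 4753 and 2011 without a low-count filter, 6443, 4716, 5393 and 2349 with unnamed loci kept, 5868, 4047, 5409 and 1865 without pseudogenes, and 7645, 6045, 6264 and 3129 with no replicate block for the pairing. The test against a log2 fold change of 1, which asks for more by construction, called 3529, 2392, 2838 and 1043, and a fit of only the tissues compared 3755, 4314 and 7364 in the first 3 comparisons. Leaving out a library or a mouse gave 2504 (without replicate 1) to 6817 (without tumour replicate 3) for tumour against adjacent; 1659 (without tail replicate 3) to 4719 (without tumour replicate 3) for tumour against tail; 2111 (without replicate 2) to 7052 (without tumour replicate 3) for adjacent against tail; 697 (without replicate 1) to 2556 (without tumour replicate 3) for tumour against both. Of the 33 lists, in the order of the first 3 comparisons, camera called 15, 20 and 13 as reported, 13, 20 and 11 with no replicate block, 0, 0 and 0 with an estimated correlation, fry 7, 11 and 8, and fry in either direction 26, 23 and 22, and leaving out a library or a mouse gave 11 to 16, 18 to 23 and 11 to 15. No called named gene or list took the opposite direction under any alternative run. Over named genes and alternatives, 246, 306 and 315 values were no longer past the threshold, 25, 34 and 17 passed it newly, and 1964, 1915 and 1788 kept their side. A left-out library costs samples by construction. For the other shifts the cause was not tested. Where a mouse was left out, 2 libraries per tissue stood for the spread of all tissues.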

Other observations

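The tests of regrouped libraries and of lymph node markers were written before their results were seen; the exchange of tissues within mice and the tests of human RNA on matrix and macrophage genes and on T, B and NK cell markers were chosen only after the result was seen. Trunk Hox genes, which mark positions along the body, included Hoxb7, Hoxb3 and Hoxb4, higher in tumour than in adjacent tissue by 3.90 ± 0.76, 2.96 ± 0.70 and 2.78 ± 0.63 on the log2 scale, while Hoxa10 fell by 1.59 and Hoxc10 by 3.13. Hoxb7, Hoxb3 and Hoxb4 were all highest in tumour replicate 3, with Hoxb7 at 22.1, 16.6 and 119.8 CPM in tumour libraries 1 to 3. The inducible heat shock genes Hspa1a and Hspa1b rose by 2.02 ± 0.59 and 4.16 ± 0.91 in tumour against adjacent tissue. Both were also highest in tumour replicate 3, with Hspa1b at 167, 259 and 1460 CPM in tumour libraries 1 to 3. Tail libraries 1 to 3 held Hspa1b at 181, 157 and 167 CPM. Mmp9, a gelatinase of the neutrophil list, rose to 57.5, 939 and 15.1 CPM in tumour libraries 1 to 3 against 12.5 ± 10.4 CPM in adjacent tissue, and Angpt2, which destabilises vessels, rose by 2.56 ± 0.46. Dbp and Hlf, output factors of the clock, fell by 3.23 and 3.14 in tumour against tail, and Per1, a core clock gene, rose by 1.68 ± 0.37 in adjacent tissue against tail. Spp1, osteopontin, rose to 608 ± 146 against 26.7 ± 15.9 CPM in tumour against tail.

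Some libraries stood apart within their tissue. Adjacent replicate 2 held erythroid and neutrophil transcripts, with list medians of 641 and 42.9 CPM against 42.3 and 0.788 CPM in adjacent replicate 1 and 1.93 and 9.11 CPM in adjacent replicate 3. Adjacent replicate 3 had interferon, macrophage and cytokine medians of 39.4, 71.0 and 6.47 CPM, against 7.17, 6.42 and 0.630 CPM in adjacent replicate 1 and 5.47, 19.2 and 0.219 CPM in adjacent replicate 2. The interferon count of tumour against adjacent tissue was 3, and 16 without adjacent replicate 3. Adjacent replicate 1 had a muscle median of 12009.8 CPM, against 4613 and 4156 CPM in the other adjacent libraries. Tumour replicate 1 had an antigen presentation median of 349 CPM, against 29.5 and 63.2 CPM in the other tumours. Tumour replicate 3 had a muscle median of 115 CPM. Tumour replicate 2 had a hypoxia median of 122 CPM against 47.5 and 47.9 CPM in tumour replicates 1 and 3. Cxcl13, a B cell chemokine chosen after its values were seen, had 4935, 7146 and 24 counts in tumour libraries 1 to 3. Of the kidney list, 3 of 16 members were tested.

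The lists not yet given, none past camera's threshold, follow as members called higher, lower and tested, with the higher and lower counts adjusted over the list alone and the camera adjusted p in brackets. Tumour against adjacent tissue: endothelial 3, 1 and 17 (3 and 1, 0.981), pericyte 1, 1 and 8 (1 and 1, 0.981), neutrophil 1, 0 and 14 (0 and 0, 0.612), T cell 3, 0 and 7 (4 and 0, 0.161), B cell 0, 0 and 4 (0 and 0, 0.981), erythroid 0, 0 and 7 (0 and 0, 0.602), epidermis 3, 1 and 19 (3 and 1, 0.568), hair follicle 2, 0 and 15 (1 and 0, 0.981), cartilage 2, 1 and 11 (2 and 1, 0.981), Schwann cell 0, 3 and 11 (0 and 3, 0.214), kidney 1, 0 and 3 (1 and 0, 0.568), posterior Hox 0, 4 and 11 (0 and 4, 0.382), anterior and trunk Hox 3, 0 and 17 (3 and 0, 0.326), immediate early and heat shock 4, 1 and 13 (5 and 1, 0.251), and rodent-expanded 2, 2 and 23 (0 and 0, 0.272). Tumour against tail: cell cycle 0, 0 and 26 (0 and 0, 0.634), respiratory chain 0, 3 and 24 (0 and 0, 0.222), pericyte 2, 0 and 8 (3 and 1, 0.355), neutrophil 4, 0 and 14 (4 and 0, 0.0829), T cell 1, 0 and 7 (1 and 0, 0.169), B cell 0, 0 and 4 (0 and 0, 0.593), erythroid 0, 0 and 7 (0 and 0, 0.372), muscle 0, 0 and 24 (0 and 0, 0.196), bone 3, 1 and 10 (3 and 1, 0.372), kidney 0, 1 and 3 (0 and 1, 0.625), anterior and trunk Hox 3, 1 and 17 (5 and 2, 0.222), clock 1, 7 and 16 (2 and 8, 0.0541), and ribosomal protein 1, 0 and 23 (1 and 0, 0.0990). Adjacent tissue against tail: hypoxia 7, 5 and 23 (9 and 5, 0.210), glycolysis 7, 4 and 15 (9 and 5, 0.196), pericyte 2, 1 and 8 (2 and 2, 0.607), macrophage 0, 1 and 20 (0 and 0, 0.990), T cell 0, 1 and 7 (0 and 1, 0.704), B cell 0, 0 and 4 (0 and 0, 0.704), NK cell 0, 0 and 6 (0 and 0, 0.196), erythroid 0, 0 and 7 (0 and 0, 0.182), cytokine 1, 1 and 19 (0 and 0, 0.383), interferon 2, 0 and 19 (1 and 0, 0.0829), antigen presentation 0, 0 and 15 (0 and 0, 0.996), adipocyte 5, 2 and 16 (6 and 2, 0.182), bone 0, 2 and 10 (0 and 2, 0.210), kidney 0, 1 and 3 (0 and 2, 0.126), renal carcinoma 1, 7 and 18 (2 and 7, 0.196), anterior and trunk Hox 1, 2 and 17 (0 and 1, 0.874), clock 4, 0 and 16 (4 and 1, 0.607), immediate early and heat shock 4, 4 and 13 (5 and 5, 0.607), ribosomal protein 0, 2 and 23 (0 and 0, 0.0980), and conserved 6, 4 and 33 (6 and 4, 0.999). Leaving out a library or mouse moved some of these by at least 3 genes and over 1.5 times. Tumour against adjacent tissue had lower endothelial 6 without adjacent 1, higher T cell 0 without mouse 1 or tumour 1 or adjacent 1, higher epidermis 0 without mouse 2 or adjacent 2, lower posterior Hox 1 without mouse 1 or 2, higher rodent-expanded 11 without mouse 3, 5 without tumour 3 and 10 without adjacent 3. Tumour against tail had lower respiratory chain 0 without mouse 1, 2 or 3 or tumour 1 or tail 2 or 3, higher neutrophil 1 without mouse 1 or 2 or tail 1 or 2, lower muscle 13 without mouse 3 and 15 without tumour 3, higher bone 0 without mouse 2 or tail 2 or 3, higher anterior and trunk Hox 0 without mouse 1, 2 or 3 or tail 1, 2 or 3, lower clock 4 without mouse 2 or tail 3. Adjacent tissue against tail had lower hypoxia 1 without mouse 1 and 2 without mouse 3 or adjacent 1 or 2 or tail 1 or 3, higher glycolysis 4 without mouse 1 or tail 1 or 2 and 3 without mouse 2, lower macrophage 4 without mouse 3 or adjacent 3, lower antigen presentation 3 without tail 1, higher adipocyte 1 without mouse 2 or tail 1, 8 without tumour 1 and 2 without adjacent 2 or tail 3, lower renal carcinoma 0 without mouse 1, 2 without mouse 2 or tail 3 and 1 without adjacent 1 or 2 or tail 1 or 2, higher clock 1 without mouse 1 or 2 or tail 2, higher immediate early and heat shock 1 without mouse 1, lower immediate early and heat shock 0 without mouse 1 and 1 without mouse 2 or tail 1 or 2, lower ribosomal protein 6 without tumour 3, higher conserved 0 without mouse 1 or 2 or adjacent 1 or tail 1, 2 or 3, 10 without tumour 3 and 1 without adjacent 2, lower conserved 0 without mouse 1 or 2, 11 without tumour 3 and 1 without adjacent 1, 2 or 3 or tail 1 or 2.

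In a few lists the median log2 fold change and the tests pointed different ways. For tumour against adjacent tissue these were glycolysis (median -0.38) and endothelial (-0.48), both up by camera, pericyte (0.09, down by camera), hair follicle (-0.55, down by camera and up by fry, and 1.89 with members at 0 in a tissue at their bound) and cartilage (-0.19, up by fry). For tumour against tail it was the kidney list (0.14, down by camera and fry). For adjacent tissue against tail they were clock (-0.16, up by camera) and macrophage (0.29, up by camera and down by fry).

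Each real split of the libraries into a pair of tissues was set against the other splits. The real values were 6326, 4589 and 5319 called genes, the highest other split gave 0 in each comparison, and 1 of 10 splits was as large, which is too few splits for a share under 0.05. For tumour against both, 1 of 30 drawn assignments of the 9 libraries, the real one, was as large as 2296, with 0 as the highest other. These draws did not keep the mice, and an assignment that mixes tissues puts their differences into the residual spread. With tissues exchanged only within each mouse, 2 of 40 drawn assignments were as large, a share that is not under 0.05. The other one, with 2823, exchanged whole tissues and so grouped the libraries as the real one did. With that renaming of whole tissues left out, a rule taken up after these counts were seen, 1 of 39 was as large. The highest other gave 383. Repeats among the remaining groupings were not removed, and assignments that mix tissues again put their differences into the residual spread. Chance therefore cannot be excluded by these draws.

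Matrix and macrophage genes were high in the tumour libraries, and human RNA counted on mouse genes is one candidate explanation. As the main source, human RNA would put these genes higher in tumour replicate 3, where the conserved genes were highest. The median log2 ratio of tumour replicate 3 to the mean of replicates 1 and 2 was -1.38 over both lists (quartiles -2.02 and -0.70). For the conserved list it was 1.63 (0.97 and 2.01). The medians were -0.71 for matrix and -2.03 for macrophage genes, and -1.04 (quartiles -2.23 and -0.49) for rodent-expanded families. These values argue against human RNA as the main source only if the conserved genes mark human RNA, which stays open. They rest on tumour replicate 3 alone and cannot exclude a human part of the matrix or macrophage counts. A higher content of mouse fibroblasts and macrophages in the tumours may account for the pattern, as a hypothesis found and examined on the same data, and a change within these cells stays open and untested.

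T, B and NK cell markers were highest in tumour replicate 1, where the list medians were 10.9, 16.2 and 14.9 CPM. The NK cell list medians were 1.99 and 1.34 CPM in the other tumours, against at most 0.0862 CPM in tail. In tumour replicate 3 that median rests on 2 to 6 counts per tested member, near the 1.00 CPM limit for a gene without counts. The members Ncr1, Klrb1c and Klre1, which were not tested, had 0 counts there. Single markers were Cd3e at 154, 17 and 6, Prf1 at 334, 41 and 2, Cd79b at 230, 6 and 2 and Ighm at 1116, 6 and 5 counts in tumour libraries 1 to 3, all chosen after their values were seen except Ighm. Human RNA cannot be told apart here: the median log2 ratio of tumour replicate 3 to replicate 1 over the markers was -3.84 (quartiles -4.44 and -2.65), but the pattern itself fixes the sign of that ratio. Lymph node tissue in that piece also cannot be told apart from lymphocytes within the tumour: over the 6 of 12 lymph node markers detected, replicate 1 exceeded the mean of replicates 2 and 3 by a median ratio of 2.18 (quartiles 1.37 and 17.0), between the bounds set for either reading. Ccl21a had 543 counts in tumour replicate 1, and Glycam1 and Cr2 were listed at 0 there. No biological explanation was tested, since the design gives none for a single mouse.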
